A study of Arabidopsis thaliana with 6 samples.

How the data were processed

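SWINGER (SWN) is a catalytic subunit of Polycomb repressive complex 2 of Arabidopsis thaliana, which methylates lysine 27 of histone H3, and VAL1 and VAL2 are related B3-domain DNA-binding repressors. Chromatin immunoprecipitation with an antibody against GFP followed by sequencing was done on seedlings 14 days old that carried SWN-GFP under the SWN promoter in a swn mutant, with VAL1 and VAL2 intact or with both mutated. These genotypes are called SWN-GFP and SWN-GFP val1 val2 below. The series held 6 samples: 2 SWN-GFP libraries, 2 SWN-GFP val1 val2 libraries and 2 input libraries, 1 of each genotype. Groups and replicate numbers were taken from the sample titles. The inputs had no file of their own here and entered no comparison.

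Each of the 4 immunoprecipitated libraries had its own peak list, so peaks were called per library and not on pooled replicates. Per the submitters' processing notes, the tools were Bowtie2, SAMtools, Picard and MACS2 and the genome build was TAIR10. Versions, settings and the input used as control for each list are not given in the sources used here. The deposited lists had no header, and their 10 columns were read in the order of a MACS2 peak table: chromosome, start, end, length in bp, summit, pileup, −log10 p, fold enrichment, −log10 q and name. The deposited pileup is a signal, the whole number of fragments over the summit, with no scaling to depth visible in the values. The −log10 p and −log10 q of each peak are the peak caller's own, and the lowest deposited −log10 q was 1.31 in 3 lists and 1.33 in the other, near a q of 0.05. The fold enrichment of each peak is the authors' ratio of the pileup at the summit to the local background. These scores were used to describe, rank or filter peaks within their own list and were not tested between lists. Where folds of both genotypes are printed together, each value belongs to its own list, whose depth and control are unknown. Coordinates are printed from the deposited lists, 1-based, in TAIR10.

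Read totals were not in the lists, so the depth of each library is unknown and no counting interval could be given. A local background was worked out from pileup and fold as (pileup + 1)/fold − 1. Its lowest value was 7.53 and 8.60 fragments in the SWN-GFP lists and 8.79 and 10.1 in the SWN-GFP val1 val2 lists, and the 4 lists rank in the same order by number of peaks. A peak missing from a list means that the caller's threshold was not passed, which depends on depth and on the control, and does not show that the protein was absent.

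Gene names and spans came from a RefSeq gene table of assembly TAIR10.1, and none of its coordinates are printed. Its fit to the lists was checked by shifting: 69.9% of the summits of SWN-GFP replicate 1 lay in protein-coding spans, against 46.7% and 46.6% after shifts of 1000 bp down or up, 49.9% and 49.1% after 2000 bp, and 59.5% and 58.7% after 5000 bp. The table gave no strand, exon or untranslated region. The design fixed before the data were examined counted a gene as occupied when a peak overlapped its span or the 1000 bp upstream. Without strand this could not be computed, so the gene span alone, which had been listed beforehand as a second setting, became the main one, and the span with 1000 bp on either side was added as an alternative after seeing the data. The location of summits was limited to gene span, gene type and distance for the same reason. The planned tests of sequence motifs in lost and gained regions were not run because no genome sequence was used here.

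Peaks of the 4 lists on the 5 nuclear chromosomes that overlapped by 1 bp or more were merged into union regions. A region or gene was called lost when both SWN-GFP lists and neither SWN-GFP val1 val2 list had a peak in it, gained in the reverse case, kept when all 4 lists had one, and mixed otherwise. The same classes were counted for the other 2 ways to split the 4 libraries 2 against 2, as a measure of the spread between libraries. Values per library were compared with an exact two-sided permutation test, whose smallest possible p is 0.333 with 2 libraries against 2, so no such comparison could pass 0.05. The labels do not say that replicates came from separate cultures, so the spread between them may be technical.

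Before the data were examined, 11 gene lists with 157 members were fixed by locus tag. BMI1B was left out because the symbols of its locus tag in the gene table contradict it, and 156 members were used. Occupancy of a list in both SWN-GFP lists was tested against all other nuclear genes, and loss against the other genes occupied in both SWN-GFP lists, with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over the lists. The lists were also described by covered length, the number of bp of the members' spans that lay under peaks, a measure added after seeing the data, as were the counts of kept genes covered less or more. For this measure, the ratio of the genotype means was compared, two-sided, with 10000 random lists drawn gene by gene from the same of 10 equal classes of mean covered length, among genes with a peak in any of the libraries. Overlapping genes were each counted. Genes and regions are not independent replicates of the experiment, so these p-values describe these libraries.

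Genes were named by a rule fixed before the data were examined: 12 loci always, the lost or gained members of each list up to 4, the 10 lost and 10 gained protein-coding genes with a symbol and the highest mean percentile of fold of their strongest peak in the lists that held it, and the 5 such kept genes. Any other gene named, including other list members, was chosen after its values were seen. Alternatives were a −log10 q of at least 5, a fold of at least 4, lists shortened to the 8189 peaks of the shortest list by −log10 p, an overlap of 50% of both peaks, merging within 500 bp, the summit inside the gene span, each replicate left out, a replicate block and, added after seeing the data, the strongest 1000, 2000 or 4000 peaks. The scripts were tested on simulated lists, in which 100% of 13169 simulated regions received their true class. Simulated peaks of a region always overlapped, and no peaks missed by the caller were simulated. That 100% therefore checks the code and says nothing on errors in the real lost and gained calls. A simulated list of 30 genes with 60% lost against 15% of the others, among 5259 genes, was called in 100% of 200 runs. With no difference it was called in 4.5% of runs. The 11 real gene lists had only 1 to 17 occupied members and were judged on p adjusted over the lists. The simulated 100% therefore does not give the power of their tests for loss. A list that did not pass for loss is not shown to lack a difference. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.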

Results

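Binding of SWN-GFP was mapped in Arabidopsis seedlings 14 days old, in 2 libraries with VAL1 and VAL2 intact (SWN-GFP) and 2 libraries of the val1 val2 double mutant (SWN-GFP val1 val2). The title of the series concerns the recruitment of SWN by VAL1 and VAL2, and the comparison between the genotypes asks where SWN is found without them. The SWN-GFP lists held 8189 and 8666 peaks and the SWN-GFP val1 val2 lists held 9177 and 9618. The sequencing depth behind them is unknown.

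Most summits of SWN-GFP peaks lay within genes in both genotypes. The summits of 69.9% and 69.5% of the peaks lay inside protein-coding gene spans in the SWN-GFP lists, and 68.0% and 67.5% did in the SWN-GFP val1 val2 lists. Moved by 5000 bp down or up, 59.5% and 58.7% of the summits of SWN-GFP replicate 1 lay there. Between 8.49% and 9.48% of the summits per list lay more than 1000 bp from any gene. Peaks overlapped 5909 and 6155 genes in the SWN-GFP lists, 5259 of them in both, and 6464 and 6815 genes in the SWN-GFP val1 val2 lists, 5636 of them in both. The mean number of peaks was 8427.5 ± 337 (SD, n = 2) in SWN-GFP and 9397.5 ± 312 (SD, n = 2) in SWN-GFP val1 val2, and peaks covered 5.71 ± 0.25 Mb and 6.15 ± 0.29 Mb (exact permutation p = 0.333 for each, the smallest possible). Among peaks with a fold enrichment of at least 4 the order was the opposite, with 2371 and 2331 peaks in SWN-GFP and 2160 and 2030 in SWN-GFP val1 val2.

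The genotypes differed in which regions and genes carried a peak by more than replicates of a genotype did. On average 78.7% of the peaks of a list overlapped a peak of the other replicate (range 75.0% to 82.2%), and 63.2% overlapped a peak of a list of the other genotype (range 57.4% to 69.1%). Of 13169 union regions, 4079 had a peak in all 4 lists, 1173 had one in both SWN-GFP lists only (lost) and 1614 in both SWN-GFP val1 val2 lists only (gained). The 2787 regions specific to a genotype compared with 236 and 227 regions specific to a pair in the other 2 splits of the 4 libraries. Of 9220 genes with a peak in any list, 3919 were kept, 844 were lost and 1184 were gained. The 2028 genotype-specific genes compared with 138 and 142 in the other splits. The excess of gains over losses was not held in all settings: with lists of equal length, which brings the counts close by construction, 1284 regions were lost and 1293 gained, and among peaks with a fold of at least 4, 574 were lost and 370 gained. Counts also rise where fewer lists must hold a peak: without SWN-GFP replicate 1 or 2, 2192 or 1934 regions were lost, and without SWN-GFP val1 val2 replicate 1 or 2, 3182 or 2795 regions and, for replicate 1, 1897 genes were gained. Genotype cannot be told apart from any batch or input that each genotype had for itself.

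**Figure D1:**
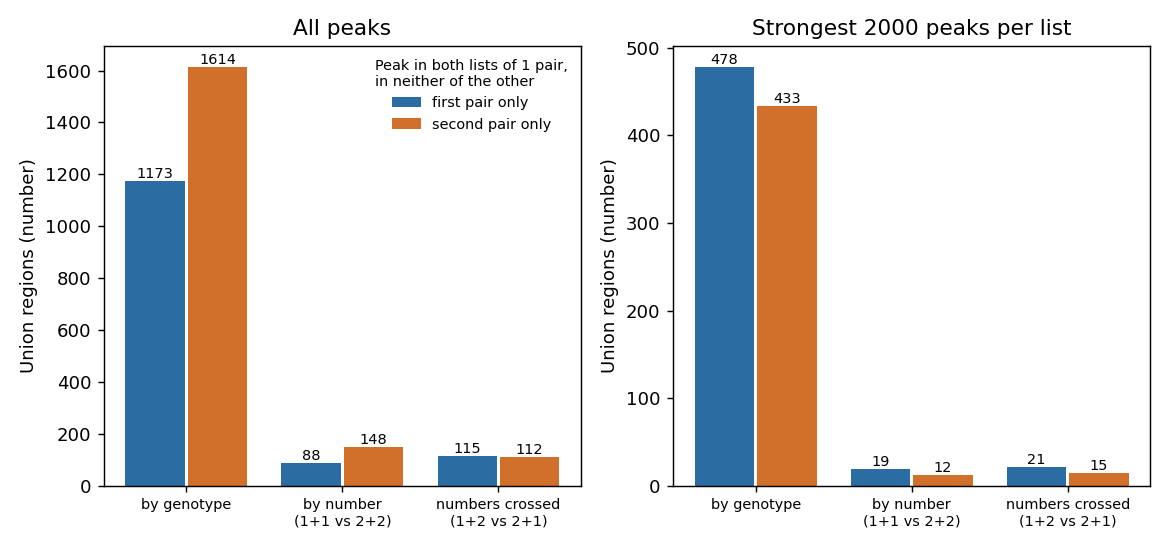
Number of union regions with a peak in both lists of 1 pair of libraries and in neither list of the other pair, for the split by genotype (first pair SWN-GFP, second pair SWN-GFP val1 val2) and the other 2 splits, with all peaks (left) and the strongest 2000 peaks of each list (right). The split by genotype gave 1173 and 1614 regions, and the other splits gave between 88 and 148 with all peaks.

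The difference between genotypes reached into the stronger peaks, although most of the strongest peaks overlapped a peak of any strength in the other genotype. With each list cut into 10 equal parts by fold enrichment, in the strongest part 100% of the peaks were found in the other replicate and 96.5% in a list of the other genotype (range 94.6% to 98.0%). In part 7, counted from the weakest, these shares were 95.8% and 71.8%, and in part 1 they were 47.5% and 40.2%. Such an overlap does not show that the peak was as strong or as broad in the other list. Among the strongest 1000 peaks of each list, a setting chosen after seeing the data, 526 of 1531 regions were kept. In that setting 272 regions were lost and 246 gained, and these can still hold a weaker peak of the other genotype. Lost peaks had a median percentile of fold of 42.2 and 45.4 within the SWN-GFP lists, against 64.1 and 66.2 for kept peaks. Gained peaks had 40.3 and 42.4 within the SWN-GFP val1 val2 lists, against 67.9 and 70.3 for kept peaks.

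**Figure D2:**
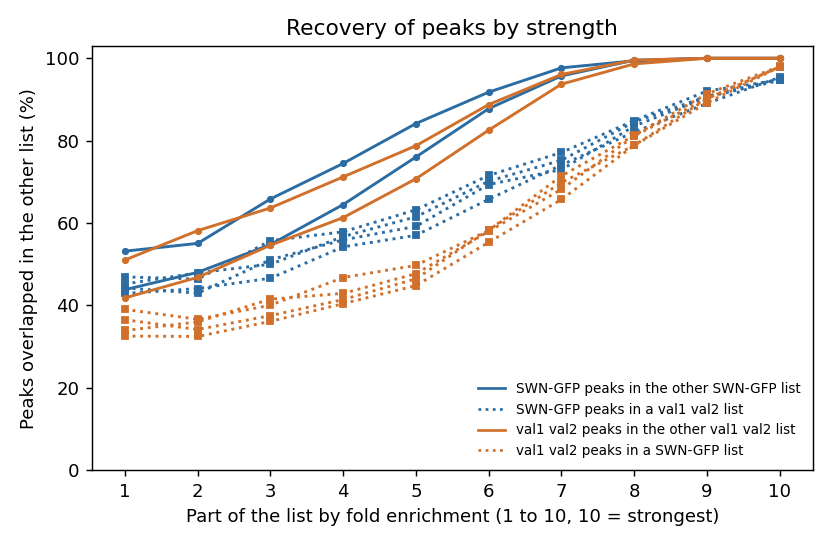
Share of the peaks of a list (%) overlapped by at least 1 bp by a peak of another list, by part of the list when cut into 10 equal parts by fold enrichment (10 is the strongest), 1 line per ordered pair of lists. The mean share in part 7 was 95.8% within genotypes and 71.8% between them.

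In plants with VAL1 and VAL2 intact, SWN-GFP occupied 8 of the 11 gene lists more often than other genes. A peak lay in both SWN-GFP lists in 13.8% to 13.9% of other nuclear genes. These include pseudogenes, of which 3813 of 3917 had no peak in any list, and were not matched to the lists by gene type or length. Among named protein-coding genes the share was about 19%. It did so in 14 of 14 floral organ identity genes, 17 of 17 meristem homeobox and boundary genes, 13 of 14 genes of auxin synthesis and transport, 14 of 16 seed storage and oil body proteins, 12 of 15 flowering time genes, 6 of 7 root patterning regulators, 10 of 15 embryo maturation regulators and 6 of 11 phase change genes. Each of these 8 lists passed Fisher's exact test, with adjusted p from 2.8e-14 for the meristem genes to 0.0024 for the phase change genes. The lists of active genes did not pass, with 1 of 15 housekeeping genes (adjusted p = 0.781 by Fisher's exact test) and 4 of 14 photosynthesis genes (adjusted p = 0.144 by Fisher's exact test). Genes of the Polycomb machinery and VAL genes did not pass either, with 2 of 18 occupied (adjusted p = 1 by Fisher's exact test).

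At the embryo maturation regulators, SWN-GFP peaks of val1 val2 seedlings covered less of several genes, while 8 of 15 members had a peak in all 4 lists. ABI3 (AT3G24650), a B3 transcription factor of seed maturation, was covered over 3561.5 ± 180 bp (SD, n = 2) in SWN-GFP and 985 ± 371 bp in SWN-GFP val1 val2. DOG1 (AT5G45830), which controls seed dormancy, was covered over 1511 ± 58 bp and 282.5 ± 58.7 bp (SD, n = 2 each). FUS3 (AT3G26790) was covered over 1869 ± 297 bp and 1043 ± 123 bp (SD, n = 2 each). Its strongest peak still ranked at percentiles 98.9 and 99.2 of fold in the SWN-GFP val1 val2 lists. There ABI3 ranked at 78.1 and 81.6 and DOG1 at 39.6 and 45.2. LEC1 (AT1G21970), a subunit of a CCAAT-binding factor that drives embryogenesis, had peaks over 1092 and 1125 bp in the SWN-GFP lists, none in SWN-GFP val1 val2 replicate 1 and 208 bp in replicate 2. LEC2 (AT1G28300) was covered over 881 ± 5.7 bp in SWN-GFP and 1273 ± 79 bp in SWN-GFP val1 val2, the opposite order. Of 13 members with a peak in any list, 7 were covered less in both SWN-GFP val1 val2 lists than in either SWN-GFP list and 2 were covered more. Among the 8 kept members 5 were covered less, against 25.7% of other kept genes, which did not pass (p = 0.031, adjusted p = 0.171 by Fisher's exact test).

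Summed over the embryo maturation list, the covered length was 15.3 ± 0.53 kb in SWN-GFP and 9.36 ± 0.23 kb in SWN-GFP val1 val2 (SD, n = 2 each), a change of -38.8%. Against random lists matched on covered length this gave p = 0.0082 (two-sided permutation over 10000 random lists) and adjusted p = 0.0902 over the 11 lists, which did not pass. Without SWN-GFP replicate 1 the adjusted p of that permutation was 0.022 and without SWN-GFP replicate 2 it was 0.038, while without SWN-GFP val1 val2 replicate 1 or 2 it was 0.246 and 0.271. No member was lost among the 10 occupied ones, where 16.1% of other genes were (adjusted p = 1 by Fisher's exact test). A list this short could not pass for fewer losses, since the unadjusted p with no member lost was 0.381 by Fisher's exact test.

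The seed storage and oil body genes, products of the late seed programme, included 3 lost members of 14 occupied ones, which did not pass against the 16.0% of other genes lost (adjusted p = 1 by Fisher's exact test). These were PER1 (AT1G48130), a 1-cysteine peroxiredoxin of seeds, with its whole span of 1299 bp under a peak in both SWN-GFP lists, and the oleosin genes OLEO1 and OLEO3. The SWN-GFP peaks over PER1 lay at chromosome 1, 17780170 to 17781880 and 17780176 to 17781820, and those over OLEO1 at chromosome 4, 12900214 to 12901105 and 12900205 to 12901058. The summed covered length of the list was 14.9 ± 0.92 kb in SWN-GFP and 9.95 ± 0.18 kb in SWN-GFP val1 val2 (SD, n = 2 each), with 9 of 15 members covered less and 1 covered more. This change of -33.1% did not pass (permutation over random lists p = 0.03, adjusted p = 0.165), except without SWN-GFP replicate 1 (adjusted p = 0.0363). With the strongest 2000 peaks of each list, a setting chosen after seeing the data, 5 of 10 occupied members were lost against 26.6% of other genes (adjusted p = 0.479 by Fisher's exact test). With all peaks but without SWN-GFP val1 val2 replicate 2, the share lost of the 14 occupied members was 35.7% (adjusted p = 0.747 by Fisher's exact test).

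**Figure D3:**
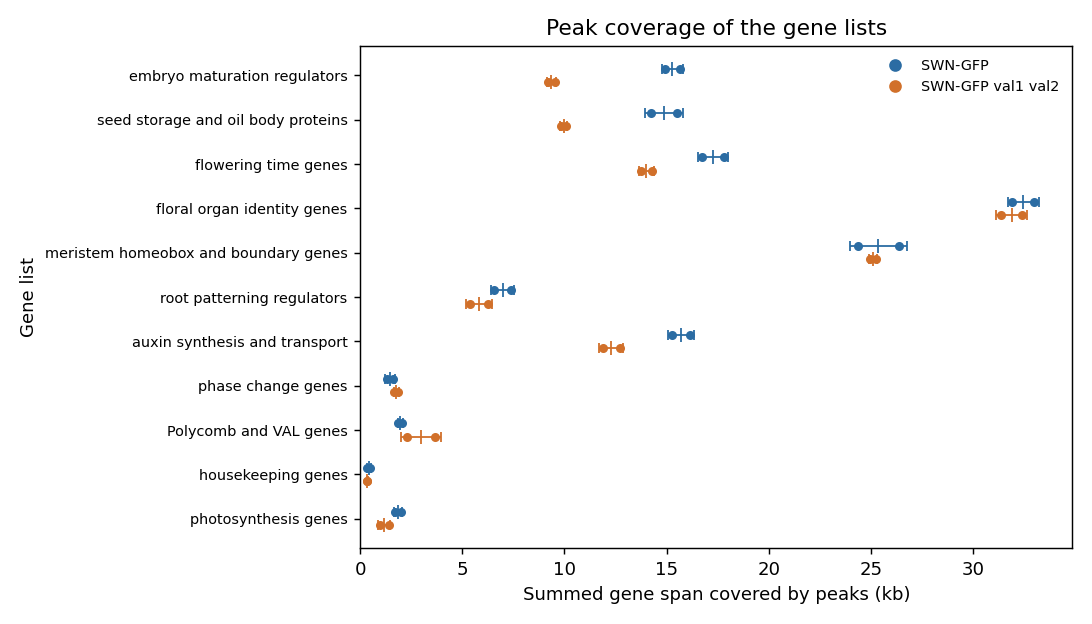
Summed length of gene span under peaks (kb) for the 11 gene lists. Points are libraries, and the bars are the mean and SD of 2 libraries per genotype. The embryo maturation regulators measured 15.3 and 9.36 kb on average in SWN-GFP and SWN-GFP val1 val2, and the floral organ identity genes 32.5 and 31.9 kb.

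At FLC (AT5G10140), the MADS-box repressor of flowering, both SWN-GFP lists held a single broad peak and both lists of the double mutant held short separate ones. In SWN-GFP the peak spanned chromosome 5, 3173262 to 3179870 in replicate 1 and 3173257 to 3179886 in replicate 2, and covered the whole FLC span of 6067 bp in both. In SWN-GFP val1 val2 the covered length was 1503 and 1716 bp, and the strongest peaks lay at 3178730 to 3179534 and 3178735 to 3179723. The authors' fold at the strongest peak was 16.6 and 15.8 in the SWN-GFP lists, where it ranked at percentile 99.5 of each list, and 4.00 and 5.42 in the SWN-GFP val1 val2 lists, where it ranked at percentiles 76.5 and 89.5.

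**Figure D4:**
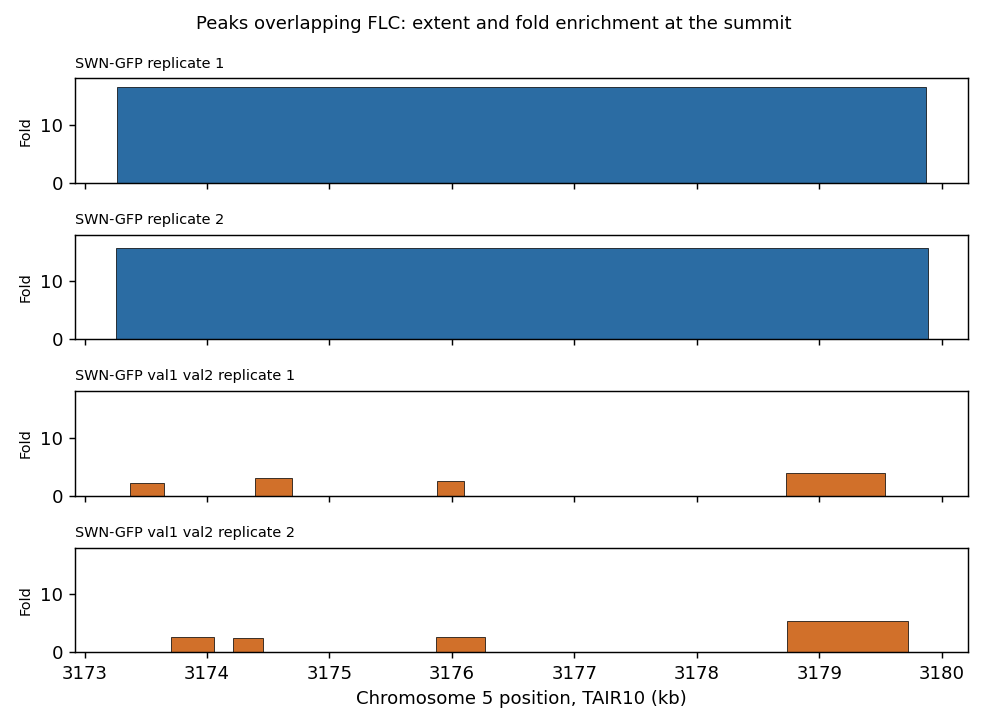
Peaks that overlap FLC in each list, drawn to scale along chromosome 5 (kb, TAIR10), with bar width the extent of a peak and bar height its fold enrichment at the summit. Both SWN-GFP lists hold 1 peak of 6609 or 6630 bp, and both SWN-GFP val1 val2 lists hold 4 peaks of 217 to 989 bp.

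The flowering time genes went both ways. MAF4 and MAF5, relatives of FLC, were lost and MAF3, which neighbours them on chromosome 5, was gained. The fold was 2.23 and 2.47 at MAF4 and 4.54 and 3.62 at MAF5 in the SWN-GFP lists, and 2.36 and 2.16 at MAF3 in the SWN-GFP val1 val2 lists. The peaks at MAF4 (percentiles 5.39 and 22.2) and MAF3 (15.1 and 7.87) were among the weaker ones of their lists. In parts 1 to 3 of a list, counted from the weakest, only 47.5% to 59.7% of peaks on average recurred in the other replicate. Weak peaks were thus often missed even within a genotype. The missing peaks of the other genotype behind these 2 calls are therefore uncertain. MAF5 ranked at percentiles 77.8 and 66.9. FT, which encodes the mobile flowering signal, had a peak only in SWN-GFP val1 val2 replicate 1. SOC1, a MADS-box promoter of flowering, was covered over 2207 ± 400 bp in SWN-GFP and 1459.5 ± 13.4 bp in SWN-GFP val1 val2, while SVP, a MADS-box repressor, was covered over 1060.5 ± 7.8 bp and 2170.5 ± 118 bp and AGL24 over 845.5 ± 161 bp and 2214.5 ± 7.8 bp (SD, n = 2 each). Of the 12 occupied members 2 were lost (adjusted p = 1 by Fisher's exact test). The covered length of the list changed by -18.8% (adjusted p = 0.343 by permutation over random lists) and by 10.8% without FLC, so the sign of the sum rested on FLC.

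**Figure D5:**
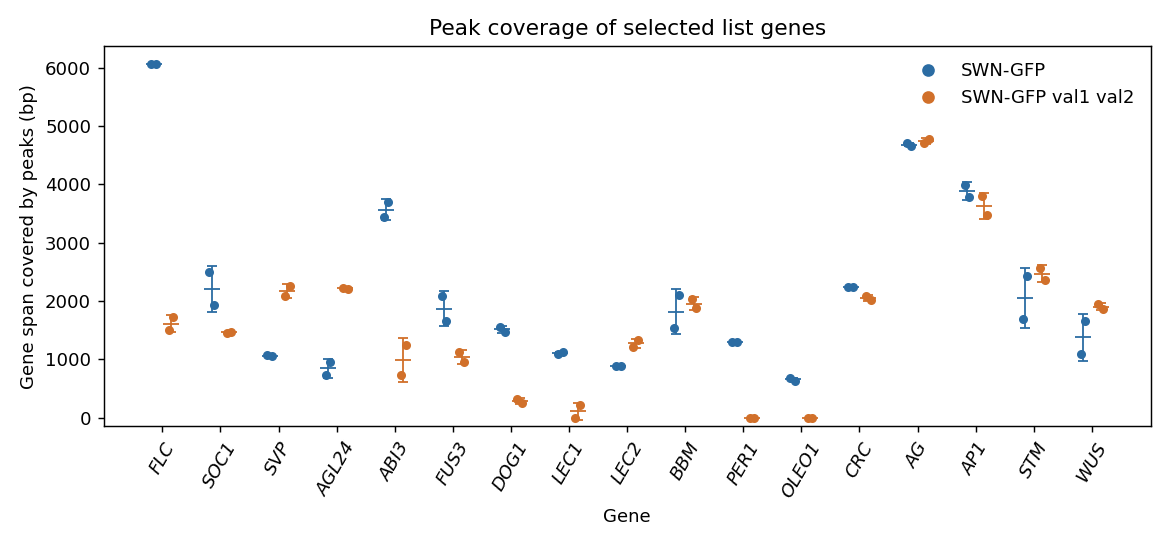
Length of gene span under peaks (bp) at 17 members of the gene lists, some of them chosen after their values were seen. Points are libraries, and the bars are the mean and SD of 2 libraries per genotype. FLC measured 6067 bp in both SWN-GFP libraries and 1503 and 1716 bp in the SWN-GFP val1 val2 libraries, while AG measured 4658 to 4775 bp in all 4.

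Floral organ and meristem regulators carried peaks in all 4 lists. All 14 floral organ identity genes and all 17 meristem homeobox and boundary genes were kept, where 16.1% of the other occupied genes were lost (adjusted p = 0.803 for each list by Fisher's exact test). With no member lost, the unadjusted p was already 0.146 and 0.0934 by Fisher's exact test. Lists this short could therefore not pass for fewer losses, and the tests do not decide whether these genes were spared. AG, which specifies stamens and carpels, was covered over 4679.5 ± 30.4 bp in SWN-GFP and 4737.5 ± 53 bp in SWN-GFP val1 val2, and STM, a homeobox gene of the shoot meristem, over 2055.5 ± 515 bp and 2466 ± 144 bp (SD, n = 2 each). The summed covered length was 32.5 ± 0.77 and 31.9 ± 0.74 kb for the floral genes and 25.4 ± 1.4 and 25.1 ± 0.21 kb for the meristem genes (adjusted p = 0.950 and 0.967 by permutation over random lists). Similar sums did not mean similar members: 8 of the 14 floral genes were covered less in both SWN-GFP val1 val2 lists and 3 more, against 25.7% of other kept genes covered less, which had the smallest p of the 11 lists and did not pass (p = 0.0124, adjusted p = 0.137 by Fisher's exact test). Of the 17 meristem genes 6 were covered less and 4 more: WOX9 was covered over 428.5 ± 10.6 and 2315 ± 105 bp, and WOX12 over 1843 ± 69 and 352 ± 48 bp (SD, n = 2 each).

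None of the remaining lists passed for loss or for covered length. Of the root patterning regulators PLT7 was lost, 1 of 6 occupied, and of the auxin genes YUC5, which encodes an enzyme of auxin synthesis, 1 of 13 (adjusted p = 1 for both by Fisher's exact test). Folds in the SWN-GFP lists were only 2.41 and 2.80 at PLT7 and 3.30 and 2.83 at YUC5. No list held either gene among its strongest 2000 peaks. The covered length of the auxin list was 15.7 ± 0.65 kb in SWN-GFP and 12.3 ± 0.59 kb in SWN-GFP val1 val2 (SD, n = 2 each, adjusted p = 0.256 by permutation over random lists), with 7 of 14 members covered less and 3 more. This change of -21.8% was -8.46% without PIN2. That of the root list was 6.97 ± 0.57 and 5.82 ± 0.62 kb (SD, n = 2 each, adjusted p = 0.557 by permutation), and the ratio of 0.836 ranged from 0.685 to 0.987 with single members left out. All 6 occupied phase change genes were kept. At the microRNA genes that set juvenile to adult timing, the fold at MIR156C was 12.0 and 11.6 in the SWN-GFP lists and 3.31 and 2.59 in the SWN-GFP val1 val2 lists, and at MIR156D it was 3.69 and 4.50 and then 11.1 and 11.5. Within their own lists, the MIR156C peaks ranked at percentiles 98.2 and 98.3 and then 62.8 and 36.8. In SWN-GFP val1 val2 replicate 1, peaks overlapped MIR156C by 24 bp only, against 104 bp in each other list. With only the strongest 2000 peaks of each list, MIR156C was lost. The MIR156D peaks ranked at percentiles 65.4 and 79.2 and then 98.5 and 98.7. Covered lengths of the phase change, Polycomb, housekeeping and photosynthesis lists gave adjusted p of 0.967, 0.557, 0.950 and 0.619 by permutation over random lists. CA1, a carbonic anhydrase gene, was the lost member of the 4 occupied photosynthesis genes, with a fold of only 2.54 and 2.99 in the SWN-GFP lists.

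Among the genes of the mutants themselves, VAL1 (AT2G30470) was gained, with peaks at chromosome 2, 12980600 to 12981116 and 12980590 to 12981127 and a fold of 3.33 and 3.47. No list had a peak in SWN or VAL2. Peaks are not a check of the genotypes, since the lists do not show whether a gene is mutated.

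The strongest lost genes were of several kinds. PLAT2, a gene for a PLAT-domain protein on chromosome 2, had peaks at 9427882 to 9429943 and 9428123 to 9429970 with a fold of 13.9 and 14.2 in the SWN-GFP lists. IAMT1, an indole-3-acetic acid methyltransferase gene on chromosome 5, had peaks at 22409186 to 22411402 and 22409345 to 22411298 with a fold of 10.8 and 9.96. PER1 and OLEO1 of the seed list ranked next to them, with LBD40, a lateral organ boundaries domain gene (fold 8.04 and 9.11), CYP94C1, a cytochrome P450 gene of jasmonate turnover (8.79 and 6.64), and the cold-regulated gene COR27 (7.44 and 6.97). SERAT3;2 and IDH-III shared the same peak (7.39 and 8.53), and emb1579 was overlapped by 55 and 18 bp only, at the edge of a peak. Of the 844 lost genes 740 were protein-coding.

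The strongest gained genes were also of several kinds. ATAF1, a NAC transcription factor gene on chromosome 1, had peaks at 269542 to 270910 and 269763 to 270925 with a fold of 8.30 and 8.65 in the SWN-GFP val1 val2 lists, which overlapped its span by 278 and 309 bp only. BET10 and TPLATE shared a peak (8.07 and 6.97) that overlapped TPLATE by 9 and 47 bp only. LBD37, a lateral organ boundaries domain gene of the nitrogen response, was covered over 1987 ± 163 bp (SD, n = 2) with a fold of 7.09 and 6.46. ALY2, DES1, TOC64-V, MYB121, MCM5 and PP2A-3 completed the 10, with folds of 4.22 to 6.60. MYB121 was overlapped by 89 and 63 bp only, and PP2A-3 by 211 and 173 bp. Of the 1184 gained genes 992 were protein-coding.

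The strongest kept genes were EMF1, which encodes a Polycomb-associated protein that represses flowering, NAC067, STY2, TT16 and AP1, a floral meristem identity gene. Folds at EMF1 were 27.5 and 25.1 in the SWN-GFP lists and 32.7 and 30.5 in the SWN-GFP val1 val2 lists, and at AP1 they were 18.5 and 17.3 and then 17.2 and 17.4. The strongest peak at EMF1 reached well beyond the gene. In SWN-GFP replicate 1 it ran from 3691694 to 3698126 on chromosome 5, while peaks covered 2553 bp of the EMF1 span. Across all 3919 kept genes the median ratio of covered length between genotypes was 1.00. Coverage was nevertheless shorter in both SWN-GFP val1 val2 lists than in either SWN-GFP list at 1011 kept genes (25.8%) and longer at 1179 (30.1%), against 16.7% by chance each way. The other 2 splits of the libraries gave 229 to 421 genes. A gene can separate the pairs in only 1 of the 3 splits, so a high count by genotype lowers the others. Those counts are therefore not an independent measure of the spread.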

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

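The 59 results were recomputed under 335 alternatives, of which 266 were labelled the same, 38 moved a value, 28 turned a direction and 3 brought a result past its threshold. For counts of regions and genes, the same meant within a factor of 1.5 of the main value. For peak number, covered length per library and overlap, it meant a difference smaller than an SD of the main values. The strongest-peak settings, the span with 1000 bp on either side, and all settings for covered length, families and pseudogene-rich bins were chosen after seeing the data. Occupancy of the 8 lists that passed held at a −log10 q of at least 5, with the wider span and without each replicate. Shortened lists lower counts by construction; other causes were not tested. The settings for motifs and for 1000 bp upstream of genes were not run, since no genome sequence or strand was used. Unknown depth limits every statement on missing peaks.

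The difference in number of peaks, SWN-GFP val1 val2 minus SWN-GFP, was 412 at a −log10 q of at least 5. At a fold of at least 4 it was -256 and that in covered length -0.147 Mb, both opposite in sign to the main values of 970 and 0.440 Mb. With an overlap of 50% of both peaks, 61.6% of peaks were shared within and 40.1% between genotypes. Summits beyond 2000 bp of any gene made up 3.05% in SWN-GFP and 3.46% in SWN-GFP val1 val2. At a −log10 q of at least 5, 1056 regions were gained. At a fold of at least 4, lost, gained and kept regions numbered 574, 370 and 1184, gained genes 385 and kept genes 1301. With the strongest 1000 peaks, lost, gained and kept numbered 272, 246 and 526 regions and 305, 282 and 601 genes. With the strongest 2000 they numbered 478, 433 and 1081 regions and 492, 454 and 1190 genes. With the strongest 4000, gained and kept numbered 757 and 2057 regions and 702 and 2155 genes. With 1000 bp on either side, 1336 genes were lost and 5943 kept. Leaving out each replicate gave 1401 to 2192 regions lost, 1901 to 3182 gained, and 1399 to 1897 genes gained, the highest without SWN-GFP replicate 1 for lost regions and without SWN-GFP val1 val2 replicate 1 for gained regions and genes, since fewer lists then have to hold a peak.

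The replicate block, counted within pairs of libraries of the same number, gave 2405 and 2532 regions lost and 3347 and 3584 gained. The numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.0035 over 13169 regions.

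For loss, no list passed in any setting, and the shares of members lost that crossed the background share were as follows. With 1000 bp on either side they were 15.4% for flowering, 50% for housekeeping (1 of 2 occupied genes) and 0% for photosynthesis genes. At equal length they were 16.7% for flowering and for root genes. With the strongest 2000 peaks they were 37.5% for embryo, 0% for flowering, 25% for root and 100% for Polycomb genes (1 gene), while the share for seed storage genes, above the background in both settings, was 50%. Without each replicate in turn they were 16.7% for root genes throughout and ranged from 16.7% to 25.0% for flowering, from 20% to 35.7% for seed storage and from 0% to 66.7% for housekeeping genes, whose occupancy ranged from 6.67% to 20%.

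For covered length, the change for the phase change genes was 23.8% at equal length and, without each replicate, 7.88% to 36.2%, on either side of the random lists. Without each replicate the change was -40.2% to -37.2% for embryo maturation genes, -35.9% to -30.0% for seed storage genes, -3.38% to -0.0971% for floral and -4.74% to 3.01% for meristem genes. The embryo list then passed without either SWN-GFP replicate and the seed storage list without SWN-GFP replicate 1.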

Other observations

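The gene families, the comparison restricted to the strongest peaks, the pseudogene-rich bins and the test of list length for the excess of gains were chosen after the values were seen; the tests of list length and background for the bins were stated before their results were seen. Among 246 families of protein-coding genes with a shared symbol and at least 8 members, the 8 with the smallest p for occupancy in both SWN-GFP lists included 6 above and 2 below the other genes. Peaks lay in 38 of 67 WRKY genes, 55 of 121 MYB genes, 26 of 41 HB (homeobox) genes, 10 of 10 LSH genes and 12 of 16 GRP (glycine-rich protein) genes and 71 of 229 CYP (cytochrome P450) genes, against about 19% of other named genes. Only 3 of 160 EMB genes, named for embryo-defective mutants, and 2 of 80 LCR genes had one. Adjusted p ran from 2.0e-09 for WRKY to 3.8e-04 for LCR and CYP by Fisher's exact test. No family passed for loss (39 tested) or for gain (173 tested). Among kept genes, 8 of 10 GRP genes were covered less in SWN-GFP val1 val2, against 29.2% of the others (adjusted p = 0.0332 by Fisher's exact test over 24 families), but 7 of the 10 lie in 2 clusters on chromosomes 2 and 5 and share their surroundings. That adjustment covered only 1 of 7 sets of family tests.

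Several genes with a peak outside the strongest 2000 in at least 1 list of the other genotype lay among the strongest 2000 peaks in both lists of 1 genotype only. Those in the SWN-GFP strongest peaks only included NAC074, which shares its strong peak with the cruciferin gene CRC (fold 14.9 and 13.5), AGP11 (11.7 and 12.6) and AUR2, an Aurora kinase gene with no peak in SWN-GFP val1 val2 replicate 2 (11.9 and 11.4). Those in the SWN-GFP val1 val2 strongest peaks only included SQN, a cyclophilin gene (13.6 and 14.0), GID1B, a gibberellin receptor gene with no peak in SWN-GFP replicate 2 (11.4 and 12.2), and IAA16, an auxin response repressor (9.05 and 9.70). With only these peaks 478 regions were lost, 433 gained and 1081 kept, and the other splits of the libraries gave 12 to 21 regions per pair. SVP differed from the genes named above in lying among the strongest 2000 peaks of all 4 lists. It had a fold of 3.99 and 4.02 in the SWN-GFP lists (percentiles 70.8 and 73.3) and 18.9 and 18.4 in the SWN-GFP val1 val2 lists (percentile 99.9 in both).

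More regions were gained (1614) than lost (1173). With lists of equal length the ratio of gained to lost regions was 1.01, but lists of equal length leave nearly as many unshared peaks to each genotype, so this value was largely set by the shortening and decides nothing. Among peaks with a fold of at least 4, of which the SWN-GFP lists held more, the ratio was 0.645. The greater length of the SWN-GFP val1 val2 lists and an effect of genotype therefore cannot be told apart for the excess of gains, while the number of genotype-specific regions, 2577 at equal length against 217 and 198 in the other splits, does not rest on list length.

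Gained regions were more frequent, relative to lost ones, in 26 bins of 1 Mb with over 40 annotated pseudogenes. These bins held 231 gained and 52 lost regions, 81.6% gained, against 55.2% elsewhere (odds ratio 3.60, 95% interval 2.64 to 4.91). The length of the lists is argued against as the whole cause, since the odds ratio at equal length was 3.47 (2.57 to 4.69), although with the strongest 2000 peaks it was lower, 2.26 (1.37 to 3.73), and leaving out each chromosome gave 3.08 to 3.92. A higher local background in the SWN-GFP lists at these bins stays open: at kept regions the log2 ratio of background between genotypes was higher there by 0.0587 (0.0381 to 0.0658), but kept regions leave out every place where a higher background would have removed a peak. This, the loss of VAL1 and VAL2 and any batch or input specific to a genotype cannot be told apart, and in the other splits of the libraries the odds ratios were 1.85 (0.579 to 5.93) and 4.35 (0.902 to 20.9) from few regions.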
